A study of Mus musculus with 6 samples.

How the data were processed

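RNA was measured in 6 whole orthotopic tumours, grown from SKOV3 cells (a human ovarian cancer cell line) injected into the ovaries of nude mice. Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was selected on its poly(A) tail, and stranded Illumina libraries were sequenced as paired reads on a NovaSeq X Plus. The groups were taken from the sample titles: 3 control tumours and 3 tumours from cells overexpressing the circular RNA circ_0005406, called circ_OE here. The titles number the tumours within each group. Nothing in the labels states that each tumour came from a different animal, so p-values measure the spread between these samples.

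The deposited table held expected counts per gene, the estimated read numbers that RSEM gives; the submitters' processing notes name RSEM and DESeq2. The authors' values were not normalised, and 22.2% of the values above 0 were not whole numbers. The same notes name the human build hg38, whereas all 56980 gene identifiers in the table were mouse Ensembl identifiers. The aligner, the annotation release and the handling of human reads are not given in the sources used here. All values below therefore describe counts assigned to mouse genes in a mixture of human tumour and mouse host RNA, and the library totals cover only that part. Of the identifiers, 55438 had a symbol in the table and 52073 were present in the GENCODE M21 annotation, so no coordinates are given, and gene classes such as pseudogene were taken from M21 by identifier. The deposited table also held the authors' mean of each group, which was used only as a check of which columns form each group. RSEM divides reads among near-identical genes, so values for pseudogenes, the H2 family, globin genes and mitochondrial genes with nuclear copies are uncertain. Circular RNAs lack a poly(A) tail and the table is at the gene level, so the overexpressed molecule itself was not measured here. Human transcripts, including human IL33, were not analysed here.

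Expected counts were rounded to whole numbers. Genes were kept with filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total count 15), which left 13190 genes. Normalised read counts are CPM, counts scaled to a common library size after TMM normalisation, given as mean ± SD with n = 3. The groups were compared with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. Replicate numbers entered no model, except in an alternative fit. DESeq2 1.42.0 was run as an alternative. On counts simulated for this comparison with 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 6% and 65% of them among 12929 genes, with 3 false calls among 74. DESeq2 recovered 26% and 84%, with 28 false calls among 138. Total counts lay between 3857037 and 6408126 per library, and 3 counts correspond to between 0.468 and 0.778 CPM, which covers counting error only.

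Before the data were examined, 33 gene lists were fixed, as were the tests, the alternatives and the rule for named genes. The lists cover pathways, RNA quality and the cell types that such a tumour can hold. They were written with human symbols and matched to the mouse symbols without regard to case, and 29 had at least 5 measured genes. These were tested with camera of limma 3.58.1, two-sided, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists tested. A shift of 1 on the log2 scale in 1 simulated list was recovered by this test (adjusted p = 6.23e-19, and 0.0144 with an estimated correlation), and 0 of the other lists passed among 28. The simulated genes were drawn independently of each other. The simulation therefore does not show how the preset correlation performs on correlated genes. Lists with 23 mouse orthologue names put in place of human names, and lists of dendritic cell markers, MHC class II genes, skeletal muscle markers and adipocyte markers, were added after the data had been seen.

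The named genes are Il33, Il1rl1, Csf1, Ccl2 and Cd163, the genes with the largest changes past the threshold and, for each list described, up to 4 members with the smallest p. As no gene passed, the rule named the 5 genes with the smallest p in each direction, with a mean of at least 1 CPM and a symbol not starting with LOC, LINC or MIR. The H2 and globin genes named, and Irf8, Erbb2, Adipoq, Cfd and mt-Co3, fall outside that rule and were chosen after their values were seen.

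The alternatives were RLE size factors, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, a replicate block, leaving out each library in turn, leaving out genes above 1% of a library's counts, an absolute log2 fold change of at least 1, DESeq2, camera with an estimated correlation, fry, and a prior count of 0.5. Added after the data had been seen were DESeq2 with each library left out, limma-voom with sample quality weights, an offset for each library's trend on gene length, the orthologue names, and camera with an estimated correlation without circ_OE replicate 3. Protein-coding genes alone, by the class in M21, were tested as a further alternative after the data had been seen, since the table itself gives no gene class.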

Results

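Gene expression was measured by RNA sequencing in 3 control tumours and 3 circ_OE tumours, all formed by SKOV3 human ovarian cancer cells in the ovaries of nude mice. The title of the series links circ_0005406 to IL-33 and to the recruitment of tumour-associated macrophages. The comparison of the groups therefore asks whether counts on the mouse genes of these processes differed. All values are counts on mouse genes. Reads of human tumour RNA may be among them, since the handling of human reads is not given. The control libraries held 4802911, 3857037 and 6408126 counts and the circ_OE libraries 3995125, 4709337 and 3925502, with 17909 to 19558 genes detected per library.

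Counts on mouse Il33 and its receptor gene showed no difference between the groups that passed the threshold. Il33 (ENSMUSG00000024810), which encodes an alarmin cytokine of the IL-1 family, was at 66.6 ± 12.6 CPM in controls and 69.0 ± 46.0 CPM in circ_OE (log2 fold change 0.05, SE 0.42, edgeR adjusted p = 0.969). The circ_OE values were 48.1, 37.2 and 121.7 CPM, and without circ_OE replicate 3 the log2 fold change was -0.65 (edgeR adjusted p = 0.35). Without control replicate 2 it was -0.10. Il1rl1 (ENSMUSG00000026069), the IL-33 receptor, had a log2 fold change of 1.12 (SE 0.66, edgeR adjusted p = 0.525), and 0.33 without circ_OE replicate 3. Of the 9 measured genes of the IL-33 pathway, 0 were higher and 1 was lower at an unadjusted p under 0.05: Myd88, the adaptor of the receptor, with a log2 fold change of -0.59 (SE 0.24). The list as a whole did not pass camera (median log2 fold change 0.28, adjusted p = 0.409).

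Macrophage genes had log2 fold changes of both signs. Cd163 (ENSMUSG00000008845), a scavenger receptor of macrophages, was at 12.7 ± 6.31 CPM in controls and 43.7 ± 36.7 CPM in circ_OE (log2 fold change 1.76, SE 0.62). Without circ_OE replicate 3 its log2 fold change was 0.87. Adgre1, which encodes the macrophage marker F4/80, was at 155.7 ± 16.2 and 100.6 ± 18.5 CPM (log2 fold change -0.63, SE 0.23). Aif1 and Laptm5 had log2 fold changes of -0.91 (SE 0.33) and -0.71 (SE 0.25). These 4 genes had an edgeR adjusted p of 0.451. Among the 21 measured macrophage markers, 1 was higher, 3 were lower and 17 were above an unadjusted p of 0.05, with a median log2 fold change of -0.12 (camera adjusted p = 0.409). With mouse orthologue names 24 were measured, 15 of them below 0, with a median of -0.23 (camera adjusted p = 0.121). Of the 14 genes of alternative (M2) activation, 2 were higher (Cd163 and Pparg, log2 fold change 0.57) and 2 were lower (Stab1, -0.86, and Tgfb1, -0.57). The median of the list was 0.27 (camera adjusted p = 0.84). The 12 genes of classical (M1) activation had a median of -0.23 (camera adjusted p = 0.194, and 0.033 with mixed fry, which counts changes in either direction). With the length-trend offset mixed fry gave 0.144.

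Among factors that recruit macrophages, those with the smallest p were lower in circ_OE. Spp1, which encodes osteopontin, was at 1455 ± 435.5 CPM in controls and 443.9 ± 151.8 CPM in circ_OE (log2 fold change -1.71, SE 0.36). Ccl8 was at 357.6 ± 39.9 and 195.1 ± 52.5 CPM (log2 fold change -0.87, SE 0.27). Ccl5, a chemokine of T cells and monocytes, had a log2 fold change of -2.06 (SE 0.37). Csf1 (ENSMUSG00000014599) and Ccl2 (ENSMUSG00000035385), the main monocyte growth factor and chemokine, had log2 fold changes of 0.42 (SE 0.31, edgeR adjusted p = 0.596) and 0.29 (SE 0.41, edgeR adjusted p = 0.786). The Csf1 value was 0.15 without circ_OE replicate 3 and 0.23 without control replicate 2. For Ccl2 this was -0.02 without control replicate 2 and -0.01 without circ_OE replicate 3. Of the 20 recruitment factors measured, 3 were lower and 0 were higher at an unadjusted p under 0.05, 2 passed when adjusted over the list alone, and 0 passed edgeR over all genes tested; DESeq2 called Spp1 (adjusted p = 0.000598) and Ccl5 (adjusted p = 0.0127). The median of the list was 0.00, its mean -0.19 and its camera direction down (adjusted p = 0.216, and 0.024 with mixed fry). Mixed fry gave 0.102 without circ_OE replicate 3 and 0.464 with the length-trend offset.

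**Figure D1:**
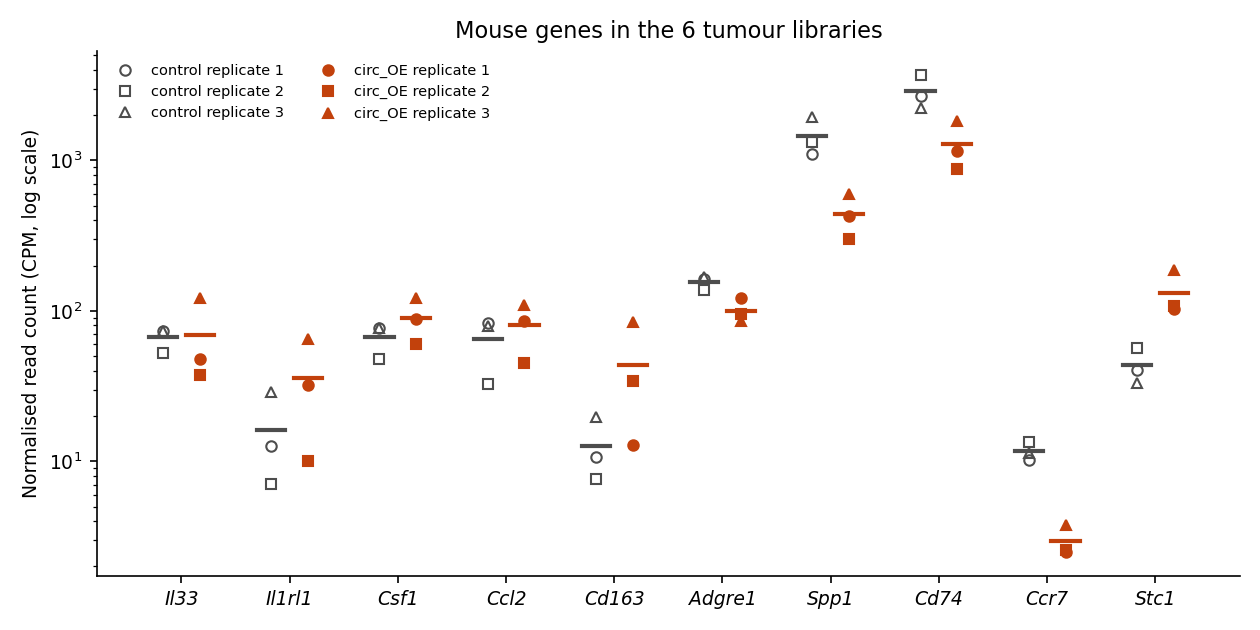
Normalised read counts (CPM, log axis) of 10 mouse genes in each of the 3 control libraries (open grey symbols) and 3 circ_OE libraries (filled orange symbols), with a bar at each group's mean. Il33 overlaps between the groups, whereas all circ_OE values of Adgre1, Spp1, Cd74 and Ccr7 lie below, and those of Stc1 above, all control values; none of the 10 genes passed the adjusted threshold with edgeR, and Spp1, Ccr7 and Stc1 did with DESeq2.

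Across all genes, edgeR called 0 of 13190 at an adjusted p under 0.05, and the smallest adjusted p was 0.451. At an unadjusted p under 0.05 there were 1423 genes, 812 higher and 611 lower, where chance gives 660. This count was 806 without control replicate 1 and 680 without control replicate 3. In 2604 genes (19.7%, against 10% by chance) all circ_OE values lay on one side of all control values. DESeq2 called 65 genes, 27 higher and 38 lower. Among the lower were skeletal muscle genes such as Acta1, H2 genes such as H2-DMb1 and haemoglobin genes such as Hba-a2. Among the higher were pseudogenes such as Gm13369. The smallest DESeq2 adjusted p was that of mt-Co3, which edgeR's filter left out. Its CPM before TMM normalisation was 0.50, 251 and 287.9 in circ_OE replicates 1, 2 and 3. In controls it was 0.31 to 0.52. Without the low-count filter edgeR called 355, and 62 to 201 in the other splits of the 6 libraries into 3 and 3. Leaving out single libraries gave between 10 and 134 calls with DESeq2, and 0 calls with edgeR, except for 1 without circ_OE replicate 1.

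The genes with the smallest p on the higher side included Stc1 (ENSMUSG00000014813), which encodes the secreted glycoprotein stanniocalcin, at 43.4 ± 11.8 CPM in controls and 131.8 ± 47.0 CPM in circ_OE (log2 fold change 1.61, SE 0.32). Car12 (ENSMUSG00000032373), a membrane carbonic anhydrase induced by hypoxia, had a log2 fold change of 2.05 (SE 0.41), and Baiap2l1 (ENSMUSG00000038859), an adaptor of the actin cytoskeleton, one of 2.32 (SE 0.41). The other 2, Gm13369 (2.27) and Gm9800 (5.69), are processed pseudogenes. On the lower side, Ccr7 (ENSMUSG00000037944), the receptor that guides dendritic cells and lymphocytes to lymph nodes, was at 11.6 ± 1.64 and 2.93 ± 0.70 CPM (log2 fold change -1.98, SE 0.34). Ccl5 was on this side too, as were Pvalb (-2.67, SE 0.44), which encodes a calcium buffer of fast muscle, and Gamt (-2.51, SE 0.40) and Hhatl (-2.55, SE 0.43). All 10 had an edgeR adjusted p of 0.451 and non-overlapping groups. DESeq2 gave an adjusted p under 0.05 for all of them except Gm9800.

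MHC class II genes were lower in circ_OE. Cd74, the invariant chain of class II molecules, was at 2885 ± 756.9 CPM in controls and 1281 ± 485.5 CPM in circ_OE (log2 fold change -1.17, SE 0.37). H2-Ab1 had a log2 fold change of -0.94 (SE 0.34), H2-Aa one of -0.97 (SE 0.39, and -0.58 without control replicate 2) and H2-DMb1 one of -1.50 (SE 0.30). With mouse orthologue names, 9 genes of the class II list were measured, 6 were lower at an unadjusted p under 0.05 and 0 were higher, with a median of -1.08 (camera adjusted p = 1.29e-05). With an estimated correlation its adjusted p was 0.715. Only 3 genes of the list were measured under the fixed human names, which left it untested there. Of the 10 genes of class I presentation, 3 were lower, among them Tapbp (-0.88, SE 0.25) and Psmb9 (-0.96, SE 0.33), and the median was -0.51 (camera adjusted p = 0.0611). With mouse orthologue names 4 of 13 were lower and the list passed camera (adjusted p = 0.00523, and 0.715 with an estimated correlation).

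Of the 29 lists tested, 3 passed camera. Genes of oxidative phosphorylation were lower, with 22 of 23 below 0 and 3 of them at an unadjusted p under 0.05. Their median was -0.54 (camera adjusted p = 0.000189, and 0.774 with an estimated correlation). Cox4i1 (-0.91, SE 0.39), Ndufs7 (-0.92, SE 0.40) and Ndufa4 (-0.77, SE 0.31) had the smallest p. Without circ_OE replicate 3 the values of Cox4i1 and Ndufs7 were -0.57 and -0.59, and without control replicate 3 those of Ndufs7 and Ndufa4 were -0.59 and -0.48. The median in circ_OE replicate 3 was -1.44 against the control mean, and -0.10 and -0.29 in circ_OE replicates 1 and 2. In control replicates 1, 2 and 3 it was -0.21, -0.21 and 0.41, so circ_OE replicates 1 and 2 lay close to control replicates 1 and 2. Without circ_OE replicate 3 the list's median was -0.28 (camera adjusted p = 0.0405). Genes of the cell cycle were lower, with 28 of 35 below 0, 5 of them at an unadjusted p under 0.05, and a median of -0.30 (camera adjusted p = 0.00986, and 0.774 with an estimated correlation). Birc5 (-1.15, SE 0.34), Ube2c (-1.11, SE 0.36) and Cdc20 (-0.93, SE 0.36, and -0.60 without circ_OE replicate 3) are mitotic genes. Without circ_OE replicate 2, in which the median was the lowest of the 6 libraries, the list did not pass (camera adjusted p = 0.637). All 11 measured mitochondrially encoded genes were above 0, 6 of them at an unadjusted p under 0.05, with a median of 1.94 (camera adjusted p = 0.00986, and 0.774 with an estimated correlation). Mitochondrially encoded genes took 6.61% of the counts in circ_OE replicate 3 and 1.26% to 1.57% in the other 5 libraries. mt-Nd5, for example, was at 3488 CPM in circ_OE replicate 3 and at 514.6 and 400.6 CPM in the others of its group; without replicate 3 the median of the list was 0.41 (camera adjusted p = 0.00891). The number of lists past camera was 5 without control replicate 1, 7 without control replicate 2, 8 without control replicate 3, 5 without circ_OE replicate 1 and 12 without circ_OE replicate 3. None passed with an estimated correlation or with directional fry.

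**Figure D2:**
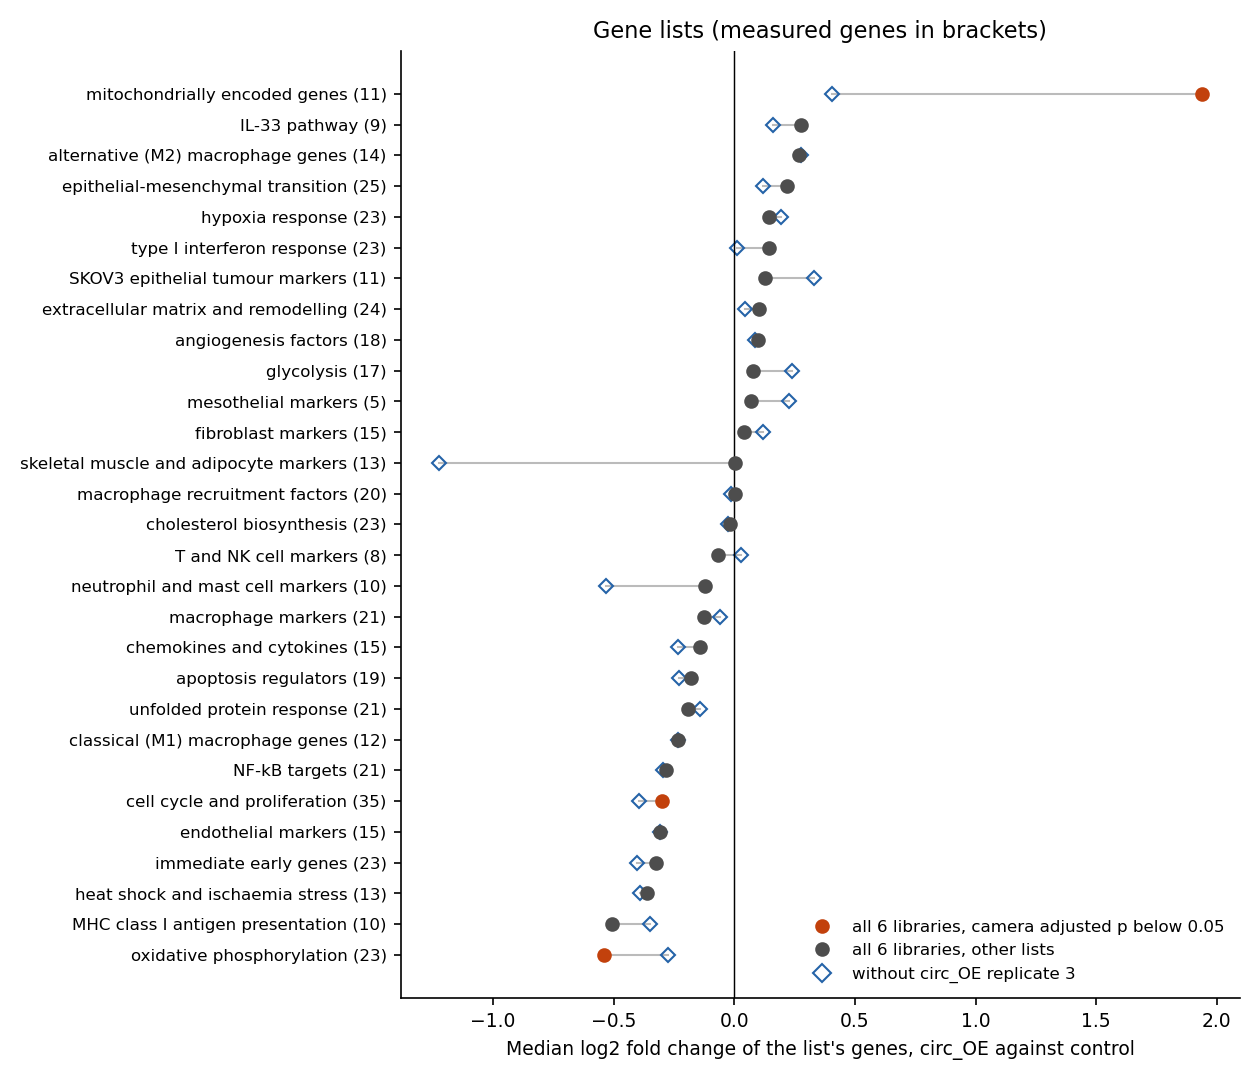
Median log2 fold change (circ_OE against control) of the measured genes of each of the 29 lists, from all 6 libraries (circles, orange where camera's adjusted p was under 0.05) and without circ_OE replicate 3 (open blue diamonds). Without that library the mitochondrially encoded genes move from 1.94 to 0.41 and the skeletal muscle and adipocyte markers from 0.00 to -1.22.

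Several lists of stress and hypoxia genes lay just above the threshold. In the hypoxia response 4 of 23 genes were higher and 0 lower at an unadjusted p under 0.05: Kdm3a (0.80, SE 0.20), Mxi1 (0.89, SE 0.30), Ndrg1 (0.80, SE 0.33) and Pfkfb3 (0.76, SE 0.32). Without circ_OE replicate 3 these were 0.86, 0.50, 0.53 and 0.32. For the list, the median was 0.15 (camera adjusted p = 0.0611). With mouse orthologue names 5 of 25 were higher and the list passed camera (adjusted p = 0.0385, and 0.74 with an estimated correlation). The further higher gene was Car12 (2.05), already named above for its small p, so this pass is not separate from that result. Of 23 immediate early genes 4 were lower, including Fos (-0.90, SE 0.27), Atf3 (-1.04, SE 0.27) and Dusp2 (-1.61, SE 0.42), and 1, Fosl1 (2.18, SE 0.68, and 0.99 without circ_OE replicate 3), was higher (camera adjusted p = 0.0611). The unfolded protein response had 5 of 21 genes lower, among them Sdf2l1 (-1.34, SE 0.38) and Herpud1 (-0.90, SE 0.28). The heat shock list had 2 of 13, Hspa1a (-1.93, SE 0.56) and Hspb1 (-1.04, SE 0.34). Its member Hspa1b had more counts than Hspa1a (3381 ± 1740 CPM in controls and 1732 ± 1066 CPM in circ_OE). For Hspa1b the log2 fold change was -0.96 (SE 0.62), with overlapping groups. Both lists had a camera adjusted p of 0.0611. NF-kB targets (median -0.28) and endothelial markers (median -0.31) had the same adjusted p. These lists passed camera without circ_OE replicate 3, as did class I presentation, although none did so with an estimated correlation. The type I interferon response (median 0.14), angiogenesis factors (0.10), extracellular matrix genes (0.10), epithelial-mesenchymal transition (0.22), glycolysis (0.08), cholesterol biosynthesis (-0.02), apoptosis regulators (-0.18) and chemokines and cytokines (-0.14) did not pass.

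Of the cell type lists fixed before, none of those tested passed camera with all 6 libraries. Without circ_OE replicate 3, the SKOV3 epithelial tumour markers (median 0.33, adjusted p = 0.0177) and the skeletal muscle and adipocyte markers (median -1.22, adjusted p = 0.00891) did, though not with an estimated correlation. The medians were 0.13 for the 11 SKOV3 epithelial tumour markers, 0.04 for fibroblast markers, -0.07 for T and NK cell markers, -0.12 for neutrophil and mast cell markers and 0.07 for mesothelial markers. The camera direction opposes the sign of the median for the T and NK cell markers (up) and the mesothelial markers (down). B cell markers, ovarian and steroidogenic markers and erythrocyte markers had under 5 measured genes, with medians of -0.55, 0.46 and -1.20. Skeletal muscle transcripts were abundant and uneven between the tumours. Acta1, the actin of skeletal muscle, was at 6160 ± 4167 CPM in controls and 1809 ± 269.9 CPM in circ_OE (log2 fold change -1.77, SE 0.48), and Ckm, muscle creatine kinase, had a log2 fold change of -1.56 (SE 0.47). Without control replicate 3, which had 10930 CPM of Acta1, these were -1.06 and -0.82. The list of skeletal muscle and adipocyte markers had a median of 0.00, a mean of -0.02 and a camera adjusted p of 0.194. The 8 skeletal muscle markers taken alone, a list added after the data had been seen, passed camera (median -0.83, adjusted p = 0.00295, and 0.361 with an estimated correlation).

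circ_OE replicate 3 stood apart from the other 5 libraries. On the first principal component of log2 CPM, which held 51.1% of the variance, it lay at 92.1 and the others between -34.0 and -9.0. Across genes, its log2 CPM correlated at r = 0.874 and 0.880 with circ_OE replicates 1 and 2, which correlated at 0.954 with each other; the control pairs lay between 0.948 and 0.959. Genes are not independent replicates, so no p is given. Its counts also followed gene length: genes of at most 1140 bases lay at a median of -0.56 (log2) from the mean of the 6 libraries, and genes of at least 5683 bases at 0.35.

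**Figure D3:**
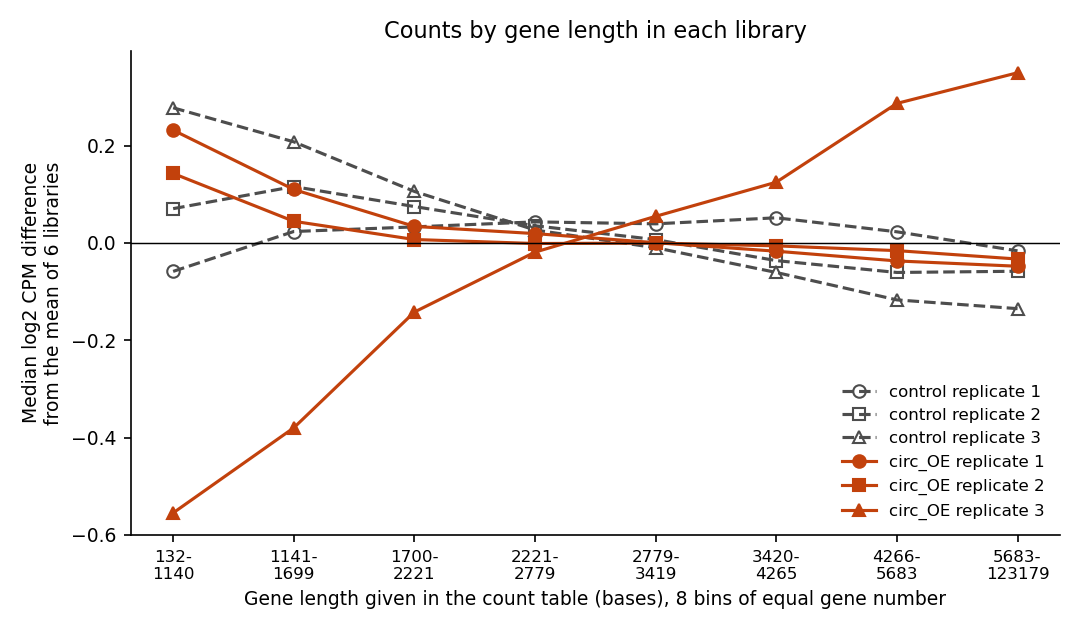
Median difference of log2 CPM from the mean of the 6 libraries (vertical axis) in 8 bins of equal gene number by gene length in bases (horizontal axis), one line per library (control dashed and open, circ_OE solid and filled). circ_OE replicate 3 goes from -0.56 in the shortest bin to 0.35 in the longest, while the other 5 libraries stay between -0.14 and 0.28.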

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

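The tests with DESeq2 and a library left out, with quality weights, with the length-trend offset, with protein-coding genes alone and with orthologue names were chosen after the data had been seen. The gene count of 0 at an adjusted p under 0.05 (edgeR; 1423 at an unadjusted p under 0.05, 65 with DESeq2) was 0 with RLE size factors, the stricter filter, the replicate block, without genes above 1% of counts, with the length-trend offset and with limma-voom quality weights, where circ_OE replicate 3 had a weight of 0.229. Leaving out 1 library gave 0 to 1. It was 355 without the low-count filter, where edgeR's prior degrees of freedom were 96.9 instead of 4.93; 59 of these 355 were among the 65 DESeq2 calls. DESeq2 called 10, 63 and 25 without control replicates 1, 2 and 3, and 124, 134 and 134 without circ_OE replicates 1, 2 and 3, with 7, 29, 14, 47, 43 and 45 of the 65 kept. The unadjusted count of 1423 was 2403 without the filter and 680 to 1722 with 1 library left out. The Il33 log2 fold change of 0.05 was -0.00058 without the filter and -0.65 to 0.35 with 1 library left out; it was negative without control replicate 2 and without circ_OE replicate 3. The number of lists past camera, 3, was 10 without the filter, 7 with orthologue names, 3 to 12 with 1 library left out, 0 with an estimated correlation, 0 with directional fry, 2 with mixed fry (classical (M1) macrophage genes and macrophage recruitment factors, neither among the 3) and 0 without circ_OE replicate 3 with an estimated correlation. B cell markers, with under 5 genes before, passed camera with the stricter filter (5 genes, adjusted p = 0.00284) and without the filter (10 genes, adjusted p = 0.0185), but not with an estimated correlation (0.584 and 0.593). The causes of these shifts were not tested beyond the values given.

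With the replicate number as a block, edgeR called 0 genes, 836 passed an unadjusted p of 0.05, and the Il33 log2 fold change was -0.13; 3 lists passed camera. Same-numbered libraries correlated at -0.08, -0.00 and -0.18 in their deviations from the group means, and 0 of 6 correlated best with their own number. These values show no sign of a pairing by number. They cannot exclude one, since circ_OE replicate 3 stood apart and so weighs on the deviations of its whole group.

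Of the other named genes, 4 changed sign when 1 library was left out: Ccl2 (range -0.0233 to 0.578), at -0.0233 without control replicate 2 and -0.0124 without circ_OE replicate 3, Erbb2 (-0.0737 to 0.592), at -0.0737 without circ_OE replicate 1, and Adipoq (-1.87 to 2.43) and Cfd (-1.73 to 2.29), at -1.87 and -1.73 without circ_OE replicate 3. Camera direction reversed, at the adjusted p given, for the SKOV3 markers (0.696) and the T and NK cell markers (0.385) without the filter, the T and NK cell markers (0.66) with the stricter filter, and cholesterol biosynthesis (0.944 with the length-trend offset, 0.974 with protein-coding genes alone). With 1 library left out, direction reversed in at least 1 fit for the following lists, with these ranges of adjusted p: IL-33 pathway 0.108 to 0.831, alternative (M2) macrophage genes 0.216 to 0.898, chemokines and cytokines 0.0768 to 0.828, glycolysis 0.0592 to 0.958, cholesterol biosynthesis 0.579 to 0.983, SKOV3 markers 0.0177 to 0.983, T and NK cell markers 0.374 to 0.993, neutrophil and mast cell markers 0.0597 to 0.958, and mesothelial markers 0.261 to 0.831. With protein-coding genes alone, by the class in GENCODE M21, edgeR called 0 of 12221 genes, 1314 passed an unadjusted p of 0.05, the Il33 log2 fold change was 0.0527 and 3 lists passed camera. In the simulation edgeR recovered 6% of genes changed 2-fold; depth and library number were not varied there.

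The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 genes at an adjusted p under 0.05, as did all 10 splits (highest other 0), and 1423 genes at an unadjusted p under 0.05, which 1 of the 10 splits reached (highest other 576). DESeq2 called 65 genes in the real split and 0 to 9 in the others. Without the low-count filter, edgeR called 355 in the real split and 62 to 201 in the others. For lists past camera, all 10 splits gave at least the 3 of the real one, and the highest other split gave 12, so the number of lists does not set the real grouping apart. The cause was not tested; the estimated correlations of the 3 lists were 0.741, 0.356 and 0.414, against the preset 0.01.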

Other observations

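The tests of depth on circ_OE replicate 3, of human RNA on pseudogenes, of the H2 locus and of macrophages, and all added lists, were chosen after the values were seen. The intervals below, except that of Cd74, come from resampling genes. They hold no spread between the tumours. Haemoglobin genes were lower in circ_OE. Hba-a2 was at 273.6 ± 121.9 CPM in controls and 57.7 ± 29.2 CPM in circ_OE (log2 fold change -2.25, SE 0.44), and Hbb-bs at 367.1 ± 161.4 and 87.2 ± 69.1 CPM (-2.08, SE 0.56). With mouse names, 5 of 5 erythrocyte genes were lower at an unadjusted p under 0.05, with a median of -2.09 (camera adjusted p = 1.29e-05, and 0.715 with an estimated correlation). Of 11 dendritic cell markers 10 were below 0, 2 of them at an unadjusted p under 0.05. The adjusted p over the 4 added lists was 0.000866 with camera, 0.0742 with an estimated correlation and 0.0203 with directional fry. Without circ_OE replicate 3 directional fry gave 0.0783, and camera with an estimated correlation 0.141. All 4 B cell markers tested were below 0, with medians of -0.56, -1.33 and -0.97 in circ_OE replicates 1, 2 and 3. The 5 adipocyte markers had a median of 1.54. The adipocyte value rests on circ_OE replicate 3, in which Adipoq was at 66.4 CPM and Cfd at 283.8 CPM; without it the median was -1.73.

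circ_OE replicate 3 lay 1.42 times as far from the other libraries as the next library did, by mean distance in log2 CPM. With each library's trend on gene length removed the ratio was 1.39 (95% bootstrap interval 1.37 to 1.41), with the trend on GC content removed 1.41, and with all libraries thinned to the smallest total 1.38. These values argue against length bias, GC bias or depth as the whole cause. A different make-up of that tumour piece or of its RNA stays open, since the design holds 1 library of it and no biological explanation was tested.

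Pseudogenes as a class were counted higher in circ_OE: 138 of 621 were higher and 10 lower at an unadjusted p under 0.05, with a median log2 fold change of 0.40 (camera p = 9.66e-11 for this single set, and 0.0431 with an estimated correlation); without circ_OE replicate 3 the counts were 187 and 11, and the medians against the control mean were 0.64, 0.44 and 0.17 in circ_OE replicates 1, 2 and 3, with 0.12 in control replicate 3. Pseudogenes took 7.19%, 7.02% and 5.82% of the counts in circ_OE replicates 1, 2 and 3, and 5.18% to 5.89% in controls. The ribosomal RNA gene Rn18s-rs5 took 5.12%, 2.78% and 0.72% in these circ_OE libraries and 1.46% to 2.04% in controls. Whether the 2 are linked was not tested. With the length-trend offset the pseudogene median was 0.48 (95% bootstrap interval 0.43 to 0.55), which argues against length bias. If reads had moved from parent genes to their pseudogenes, the parents were predicted to be lower. The 91 parents tested had a median of 0.14 (0.07 to 0.18) without circ_OE replicate 3, against 0.53 for the pseudogenes named after parent genes. This cannot decide the question. The levels of parents and pseudogenes were not compared, and a small share of a parent's reads could raise a pseudogene while the parent hardly changes. Human tumour RNA counted on mouse genes may contribute: mouse Erbb2 was at 296.4 to 738.7 CPM and Krt8 at 283.3 to 448.7 CPM across the 6 libraries, and the medians of 11 SKOV3 epithelial tumour markers against the control mean, with the length trend removed, were 0.35, 0.33 and -0.11 in circ_OE replicates 1, 2 and 3, where the pseudogene medians were 0.47, 0.37 and 0.74. The marker median of replicate 3 was opposite in sign to its pseudogene median, with an interval of -0.92 to 0.31. Without the length correction the marker medians were 0.33, 0.28 and -0.43, and the pseudogene medians 0.64, 0.44 and 0.17. Replicate 3 was then the lowest circ_OE library in both, so these values do not decide on human RNA. An effect of circ_0005406 stays open too.

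The 7 MHC class II genes listed after their values were seen, which leave out H2-Ea (log2 fold change -2.14, SE 1.02), were all lower in circ_OE at an unadjusted p under 0.05, with a median of -1.17. With the length-trend offset the median was -0.92 (95% bootstrap interval -1.31 to -0.83), which argues against length bias. A variant of the H2 locus between animals may account for H2-Ea and H2-Eb1. In circ_OE replicate 1 they were at 3.89 and 8.06 CPM, against at least 521.6 and 843.2 CPM in each control. H2-Aa was at 1033 CPM in that library, and the annotation classes H2-Ea as a polymorphic pseudogene. Cd74, which lies outside the locus, was lower too (log2 fold change -1.17, 95% interval -2.0 to -0.35). Such a variant alone does not account for Cd74. Cd74 is 1 gene, tested after its value was seen (edgeR adjusted p = 0.451), so it cannot decide for the whole class. A variant of the locus stays open for the other class II genes. An even loss of macrophages would lower the macrophage markers by about as much as the class. Their median was -0.12 (-0.38 to 0.21), with 12 of 21 below 0 and the lowest, Aif1, at -0.91. With mouse names it was -0.23 (-0.47 to 0.09), with 15 of 24 below 0. The markers had both signs (Cd163 1.76, Adgre1 -0.63), and the test was set after these values were seen. They show only that the markers as a set fell less than the class, and fewer macrophages stay open. Fewer dendritic cells stay open, since the median of 11 dendritic cell markers was -0.52 (-0.65 to -0.42), with Irf8 at 86.8 ± 2.24 and 60.6 ± 4.10 CPM, and that interval spans the bound of -0.5 set for this test; fewer B cells and an effect of circ_0005406 were not tested and stay open too.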
